A study of Mus musculus with 9 samples.

How the data were processed

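Gene expression was measured in 3T3-L1 cells, a mouse preadipocyte line that turns into fat-storing adipocytes when hormonal inducers are added to the confluent culture. The 9 samples were 5 cultures in additive-free medium (days 0, 2, 4, 6 and 8) and 4 in medium with 0.5% CP (days 2, 4, 6 and 8). The sample titles call the second medium Chickpea, and the labels do not say what the preparation contained. Each medium and day had 1 array, so differences between cultures and between arrays are not separated, and days are not replicates of each other.

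The arrays carried 321 metabolic syndrome genes with 1 spot each and 10 control probes. RNA was labelled with 1 dye, per the labels. Spot intensity was scanned with GenePix Pro 6.1.0.4, per the file headers, which give the median pixel intensity minus the local background. The deposited value table holds intensity on a linear scale. How the authors made it is not given in the sources used here, and it was worked out from the values. Each value equalled the background-subtracted intensity plus 2 or 3 units, multiplied so that the 4 Gapdh spots of each of 2 blocks averaged 10000. All 354 value table entries matched 1 spot each within a relative tolerance of 1e-06, and they were named through that match. The scanner wells carry names that match no sample label, so the deposited table was the source of the values. Each sample was tied to 1 well only through its values (354 entries matched, against 1 or 2 in the next best well). Intensities given in units rest on that match. The scanner table had been the intended source, but no background correction could then be varied. Of the array's gene names, 318 were current symbols and 13 were synonyms. No genome build or coordinates are given in the sources used here.

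Deposited intensity was converted to log2, spots of a probe were averaged, the brightest probe stood for a gene, and arrays were quantile normalized. A spot counted as above the limit at more than 10 intensity units. That limit was chosen after the files had been seen, and 3 of 369 empty and negative control spots exceeded it. Values were then floored at log2 3.39, the highest over arrays of the lowest value among genes above the limit. A difference between arrays with 1 side at the floor is a bound on its size, written "at least" or "or lower", and so is the chickpea effect of such a gene, the mean of the 4 same-day differences. With both sides at the floor on a day, that day's 0 is not a measured difference and the mean is no bound. Fitted day 8 differences are not bounds. Genes needed to be above the limit on 2 arrays. Of the 247 that were, 8 were constant at the floor after scaling, leaving 239 tested.

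The number of arrays limits the precision. The chickpea effect was fitted with limma 3.58.1 (lmFit and eBayes, R 4.3.3) on the 8 arrays of days 2 to 8 with day as a block, leaving 3 residual degrees of freedom. It asks whether the mean same-day difference exceeds its own variation between days. A second limma fit tested a linear change of that difference with day (2 residual degrees of freedom). The third compared day 8 with day 0 over all 9 arrays with additive terms for day and medium (3 residual degrees of freedom), assuming 1 chickpea effect for all days. Its day term fits the single day 0 array exactly, so its SE and p rest on how the chickpea difference varies between days 2 and 8. They assume that the day 0 array varies like the others. The median residual SD was 0.38 in this and in the chickpea fit. Tests were two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. Differences on a single day have no test. Pairing of arrays by day comes from the labels.

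Of 30 gene lists, 15 had at least 5 tested members. They were tested with camera at a preset correlation of 0.01 and with an estimated correlation, and with fry. With an estimated correlation, camera takes its p from the residual degrees of freedom, 3 here, so its power is low. For insulin signalling with chickpea the estimated correlation was -0.02, yet the camera p rose from 0.0692 to 0.138. List members said to rise or fall are those past the test. An exact sign-flip test over the 4 days cannot give a p below 0.05. Medians during differentiation were ranked among 10000 random lists matched on mean level. The position on the differentiation axis is the slope, across genes, of the chickpea minus control difference against the control change from day 0 averaged over the other days.

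Sample groups, designs, lists, most alternatives and the rule for naming genes were fixed before the data were examined. The rule names the 10 largest increases and 10 largest decreases with the same sign on all 4 days (for differentiation, on both day 8 arrays), filled with genes that did not pass where fewer did, and 29 genes fixed by name, of which 27 were on the array. Some genes that the rule names are not reported here. Alternatives covered scaling, filter, spot averaging, variance prior, array weights, the day block and leaving out days or arrays. Having no floor and a filter limit of 20 units were added after seeing the data.

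The fits were tested on simulated data with the design and spread of the 239 genes. For the chickpea effect, 64% of genes changed by log2 1 were called, 93.8% by log2 2 and 98.5% by log2 3, against 1.62% of unchanged genes. For differentiation the shares were 9.75%, 59.8% and 88.3%, against 0.782%. For the change with day, 99.8% of genes with a slope of log2 1 per day were called, against 1.45%. That was the smallest slope simulated, and of the slopes named below only that of Trib3 reached it, so recovery of smaller slopes is not known. Each simulation changed 20 of the 239 genes at each size. These simulations assume independent normal errors. Figures were drawn with matplotlib 3.10.9, and tables were read with pandas 2.3.3 in Python 3.11.15.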

Results

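RNA from 9 cultures of 3T3-L1 cells was measured on 1 array each: 5 in control medium on days 0 to 8 and 4 in chickpea medium on days 2 to 8. The share of the 321 metabolic genes above the limit was between 62.3% and 73.2% per array. Median spot intensity in control medium was 57 units on day 0, 47 on day 2, 129 on days 4 and 6 and 168 on day 8. In chickpea medium it was 83 on day 2, 55 on day 4 and 64 on days 6 and 8, so the chickpea arrays were dimmer from day 4 on. There were no replicate cultures for any medium and day.

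On day 8 of differentiation against day 0, 2 of the 14 adipocyte markers passed the test upward, and all 14 were at least 2-fold higher in control medium. However, 0 genes passed with limma on the deposited values, with control gene scaling or without scaling (49, 34 and 29 at an unadjusted p under 0.05). The list did not pass camera with an estimated correlation (adjusted p = 0.270). Lipe, hormone-sensitive lipase, rose by log2 5.16 ± 0.37 (SE; limma adjusted p = 0.00497). Plin1, which coats lipid droplets, rose by 4.46 ± 0.58 in the fit (adjusted p = 0.0388), and Pcx, the pyruvate carboxylase gene, by 4.12 ± 0.30 (adjusted p = 0.00497). Sfrp2, a secreted Wnt modulator, fell, with a fitted difference of -3.40 ± 0.34 (adjusted p = 0.0151), and so did Gata2, a transcription factor of preadipocytes, at -1.88 ± 0.27 (adjusted p = 0.0494). Both downward calls were lost under the 5 other scalings. These 5 of 239 genes passed, and 56 had an unadjusted p under 0.05. The SE and p of these differences hold no measured spread of day 0, which had 1 array.

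Other adipocyte genes had large day 8 estimates that did not pass the test. They were 7.44 ± 1.61 for Cfd (adipsin), 7.40 ± 1.65 for Adipoq (adiponectin), 6.20 ± 1.01 for the fatty acid binding protein Fabp4, 5.49 ± 1.58 for the fatty acid transporter Cd36 and 5.60 ± 1.47 for Retn (resistin), with adjusted p from 0.0527 for Fabp4 to 0.128 for Cd36. Cfd, Adipoq, Cd36 and Retn were not above the limit on day 0, and their measured day 8 differences in control medium were at least 8.03, 7.28, 6.00 and 6.17. Acsl1, Hsd11b1 and Agt had estimates of 4.54, 4.61 and 3.76, Lpl and Pnpla2 of 2.93 and 3.47, Slc2a4 of 2.96, Pparg of 2.10 and Cebpa of 1.32. For Agt the measured day 8 difference in control medium was 2.50. Its chickpea difference changed with day, while the fit assumes 1 effect for all days. Below 0 were Thbs1 at -3.42, Pdk4 at -2.42, Vegfd at -2.38, Apod at -2.33, Vegfc at -2.27, Thbs2 at -2.27, Lox at -2.20 and Map2k6 at -1.71, none past the test, as were Ccl2 at -1.60, Dlk1 at -1.17, Ppargc1a at -1.09 and Irs1 at -1.06. Fasn, Acaca and Srebf1 had estimates of 0.92, 0.66 and 0.79, and Insr of -0.81. Cebpb, Cebpd and Ucp2 lay between -0.42 and -0.25. Il6 was at the floor on every control array, so no day 8 difference was measured. Lep, the leptin gene, was at the floor on every array after scaling and was not tested.

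The adipocyte marker list had 14 tested members, and all 14 were at least 2-fold higher in control medium on day 8 than on day 0. Their median difference was at least log2 4.79, since only 6 of the 15 markers on the array were above the limit on day 0. In the fit 2 of the 14 passed the test upward, and 11 adjusted over the list alone. Camera gave an adjusted p of 6.43e-13, and adjusted p = 0.270 with an estimated correlation. Further lists passed camera upward. In lipolysis 2 of 6 members passed the test (3 adjusted over the list alone), with camera adjusted p = 0.00460. In fatty acid uptake and binding it was 0 of 8 (4 adjusted over the list alone), with 0.00460. In lipogenesis it was 0 of 7 (1 adjusted over the list alone), with 0.0267. In adipokines it was 0 of 11 (3 up and 1 down adjusted over the list alone), with 0.0267. At least 2-fold higher in control medium on day 8 were 4 members of lipolysis, 4 of fatty acid uptake and binding, 2 of lipogenesis and 7 of adipokines (1 lower). Each of these lists had adjusted p = 0.270 with an estimated correlation, so none passed that version. Lipogenesis lost its call at an estimated correlation of -0.12, so the loss does not come only from correlation between genes. For the adipocyte markers, however, the estimated correlation was 0.82, far above the preset 0.01. The preset camera p of that list leaves out most of this correlation. Estimates were 0.23 for fatty acid uptake and binding and 0.13 for lipolysis and adipokines. Among the random lists, the adipocyte marker median ranked at percentile 100 on all 4 days. Lipolysis ranked from 99.4 to 99.98, fatty acid uptake and binding from 98.83 to 100, lipogenesis from 97.07 to 98.3 and adipokines from 98.47 to 99.97. Adipogenic transcription factors, which did not pass camera, ranked from 95.68 to 99.97. This ranking ignores correlation between the genes of a list. Lists share members. Also adipocyte markers are Lipe, Pnpla2, Adrb3 and Plin1 of lipolysis, Cd36, Fabp4 and Lpl of fatty acid uptake and binding, and Adipoq, Retn and Cfd of adipokines. These lists are therefore not separate from the marker list. The count of 5 genes also depended on which arrays entered the limma fit. It was 0 without the control day 4, control day 8 or chickpea day 4, 6 or 8 array. From 36 to 57 genes then had an unadjusted p under 0.05 (limma). The count was 2 without control day 6, 28 without control day 2 and 26 without chickpea day 2. Leaving out 1 array of day 2, 4 or 6 also takes its same-day partner out of the estimate of the spread. The fitted differences were then the same whichever medium was left out (Cebpb -0.53 without either day 2 array). For these days the counts therefore reflect day pairs and the filter rather than single arrays.

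**Figure D1:**
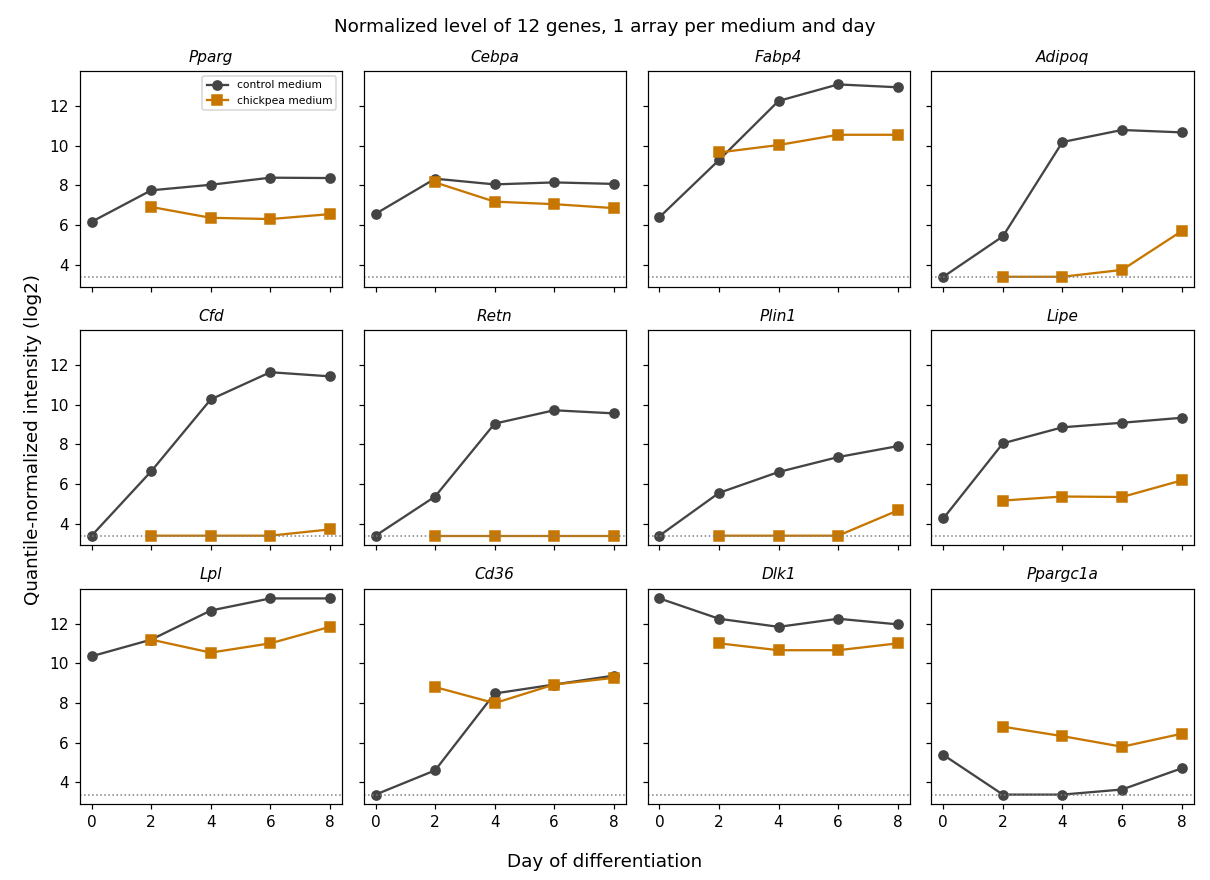
Quantile-normalized intensity (log2, vertical axis) of 12 genes by day of differentiation (horizontal axis), 1 array per point, in control medium (circles) and chickpea medium (squares); the dotted line is the floor at 3.39. On day 8 Lipe was at 9.33 in control and 6.18 in chickpea medium, and Adipoq at 10.67 and 5.69.

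With chickpea, 6 of the 14 adipocyte markers passed the test downward over days 2 to 8, but the list did not pass camera with an estimated correlation (adjusted p = 0.468). Lipe fell by 3.32 ± 0.21 (SE; limma adjusted p = 0.00411) and was lower on 4 of 4 days. Plin1, Cfd, Adipoq and Retn also fell, with log2 differences at or below -3.14 ± 0.32 for Plin1 (adjusted p = 0.0102), -6.52 ± 0.89 for Cfd (adjusted p = 0.0173), -5.22 ± 0.91 for Adipoq (adjusted p = 0.0288) and -5.03 ± 0.82 for Retn (adjusted p = 0.0256). Cfd was above the limit on 1 of 4 chickpea arrays, Adipoq and Plin1 on 2 and Retn on 0, against 4 of 4 control arrays each. Where chickpea values lie at the floor, as for Cfd on days 2, 4 and 6, SE and p follow the control arrays' change with day. Pparg, the master regulator of adipogenesis, fell by 1.60 ± 0.25 (adjusted p = 0.0248).

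Among further genes that fell were C3 (complement) at -4.17 ± 0.35, Hp (haptoglobin) at -4.37 ± 0.64 or lower, Acsl1 (acyl-CoA synthesis) at -3.33 ± 0.39, Dpt at -3.12 ± 0.63 and Apod at -2.99 ± 0.42. The others were Pcx at -2.38 ± 0.17, Acadm (medium-chain fatty acid oxidation) at -1.81 ± 0.31, Dlk1 (a preadipocyte marker) at -1.24 ± 0.18 and Vegfc at -0.88 ± 0.20, and each of these genes was lower on 4 of 4 days. Higher under quantile scaling were Ppargc1a, a coactivator of mitochondrial genes, by at least 2.57 ± 0.33 (adjusted p = 0.0141), Hmox1, heme oxygenase, by 2.37 ± 0.48, Gk (glycerol kinase) by 2.15 ± 0.42, Mif by 1.75 ± 0.18, Pi4k2b by 1.49 ± 0.27, Vegfb by 1.47 ± 0.17, Insr, the insulin receptor, by 1.33 ± 0.24, Cap1 by 1.25 ± 0.15 and E2f5 by at least 1.21 ± 0.21, each higher on 4 of 4 days. Differences that did not pass were Cebpa at -0.84 (adjusted p = 0.0635), Cebpb at 0.88, Fabp4 at -1.69 (0.0876), Lpl at -1.46, Slc2a4 at -2.36, Pnpla2 at -1.41, Srebf1 at -0.93, Cebpd at -0.70, Fasn at -0.70, Irs1 at 0.48, Ccl2 at 0.39, Acaca at 0.19 and Ucp2 at 0.06. Cebpd was at the floor on chickpea days 4, 6 and 8 and control day 8, and Slc2a4 on all 4 chickpea arrays and control day 2. Their means therefore include a day with no measured difference and are not exact. Il6 was at 0.05, which rests on day 2, the only day on which it was above the floor. Cd36 was at 0.90, with 4.20 on day 2 and -0.49, 0.00 and -0.11 after.

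In all, 36 of 239 genes passed, 21 higher and 15 lower, with 95 at an unadjusted p under 0.05. That count rests on the days and the scaling. It was 0 without day 4 (47 at an unadjusted p under 0.05, limma) and 4 without day 6, each leaving 2 fewer arrays, and 71 without day 2. The split turned with scaling: 7 higher and 23 lower with median scaling, 13 and 22 with 75th percentile scaling, 1 and 34 with control gene scaling, 1 and 6 on the deposited values and 0 and 15 unscaled. Apod, C3, Cfd, Lipe, Pcx and Plin1 were called lower under all 6 scalings, and 0 genes were called higher under all 6. The median of all tested genes was 0.21 with quantile scaling and -0.38 with control gene scaling, so the direction of genes with small differences depends on the scaling. Of the 9 control genes, 0 passed, but 7 were above 0 with quantile scaling, led by Endog at 0.77, Rps18 at 0.75 and Hprt at 0.68, each higher on 4 of 4 days. With control gene scaling 6 were above 0, and Endog was at -0.32, Rps18 at 0.42 and Hprt at 0.06. Gapdh was at -0.20 with quantile scaling and 0.07 with median scaling. It was at 1.81 on day 8 against day 0, falling to 1.07 with median scaling.

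**Figure D2:**
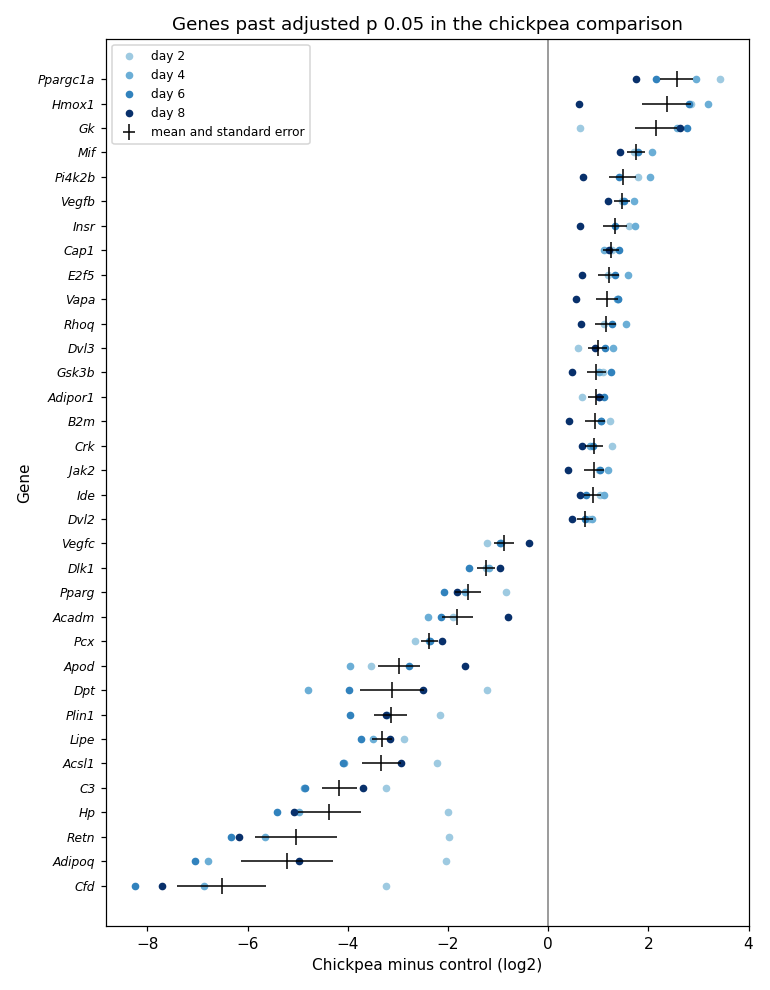
Chickpea minus control difference (log2, horizontal axis) of 34 of the 36 genes past adjusted p 0.05 with quantile scaling, 1 gene per line; points are the 4 days, and the bar is the mean with its standard error. Cfd lies lowest at -6.52 and Ppargc1a highest at 2.57.

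Of the adipocyte marker list, 6 of 14 members passed the test downward, 12 adjusted over the list alone, and 13 had differences below 0. Adrb3 is among the 13, though both media were at the floor for it on days 2, 4 and 6. Markers at the floor also make the list medians inexact. The list medians were -0.13 on day 2, -2.19 on day 4, -3.13 on day 6 and -2.78 on day 8, an average of -2.06 ± 1.34 (SD over 4 days; the exact sign-flip test gave the smallest p that 4 days allow, which is above 0.05). Camera gave adjusted p = 1.18e-07 at the preset correlation of 0.01. With the estimated correlation, 0.82 for this list, its adjusted p was 0.468. Lipolysis (2 of 6 fell, 3 adjusted over the list alone) had camera adjusted p = 0.0183, and adjusted p = 0.468 with an estimated correlation. It shares Lipe, Pnpla2, Adrb3 and Plin1 with the markers. In insulin signalling 4 of 25 rose (4 adjusted over the list alone, Insr and Gsk3b among them), with adjusted p = 0.176, and in the AMPK pathway 2 of 9 rose (4 adjusted over the list alone; Ppargc1a, Adipor1), with adjusted p = 0.176. The median of insulin signalling was 0.48 with quantile and -0.28 with control gene scaling, and that of the AMPK pathway 0.26 and -0.28. Inflammation (17), lipogenesis (7), fatty acid oxidation (8), fatty acid uptake and binding (8), adipokines (11), adipogenic transcription factors (9), inhibitors of adipogenesis (8), nuclear receptors (11), glycolysis (12), inducer response (8) and candidate control genes (7 tested members) had camera adjusted p from 0.174 to 0.882. By fry, which asks whether a list's genes move 1 way on balance without comparing them with other genes, adjusted p was 0.0438 for adipocyte markers, 0.0120 for lipolysis and 0.0270 for adipogenic transcription factors, all downward, and 0.00734 for insulin signalling, 0.00734 for the AMPK pathway and 0.0120 for inflammation, all upward. For inflammation the directions differ, with a median of 0.05, a mean of -0.07 and camera downward. The other lists had fry adjusted p from 0.0556 for lipogenesis to 0.942 for inhibitors of adipogenesis. Among them, the candidate control genes were upward (fry adjusted p = 0.0735). Fry was run with quantile scaling alone, where the median of all tested genes was 0.21. The medians of insulin signalling and the AMPK pathway were 0.48 and 0.26 there. The muscle list had 0 tested members and the hepatocyte list 2.

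On single days, the chickpea array had 48 genes at least 2-fold higher and 44 lower than control on day 2, 54 and 39 on day 4, 46 and 33 on day 6 and 34 and 31 on day 8, of 247; with no replicate these describe the arrays. Across genes, the difference ran, on the log2 scale, against the control change from day 0: the slope was -0.15 on day 2 (Pearson r = -0.18), -0.59 on day 4 (-0.53), -0.70 on day 6 (-0.62) and -0.60 on day 8 (-0.64). Spearman's rho was weaker, at -0.05, -0.29, -0.38 and -0.41, so the slopes rest in part on the genes with large changes. Genes are not independent replicates, and the day 0 array enters each slope only through the axis. In control medium, 36 genes were at least 2-fold higher and 35 lower than day 0 on day 2, 30 and 35 on day 4, 38 and 49 on day 6 and 40 and 53 on day 8.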

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

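The tests of scaling and of the stress gene group in this part were chosen after the result was seen, while those of dimmer signal and of other splits were written before. After their values were seen, the rule for deciding the stress gene test was changed from excluded to undecided, and that for dimmer signal gained a condition on the quartiles, which left its outcome as it was.

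The difference between the media changed with day for 8 of 239 genes (limma, 75 at an unadjusted p under 0.05), which is why they are listed here. Per day, the slopes were -1.06 for Trib3, 0.82 for Agt, 0.59 for Rab3il1, 0.57 for Scara3, 0.55 for Rgs2, -0.51 for Lgals12 and 0.47 for Acat2, and 1 further gene is not named because its array name is an old symbol shared by different genes. Trib3 went from 4.64 on day 2 to -1.84 on day 8, and Agt from -3.96 to 0.97. Lgals12 was at the floor on all 4 chickpea arrays, so its slope follows the control arrays. The count was 3 with median scaling and 0 on the deposited values. Of the 8 splits of the arrays that part all 4 day pairs, 1 (the real one) gave 8 genes and the highest other gave 0, but 8 splits are too few for a share under 0.05. The other splits also swap the media on some days, which turns a steady difference into spread.

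The lower adipocyte markers were weighed against technical explanations. Their median was -2.03 with quantile scaling and -2.08 or lower under the 5 other scalings, and 13 of 14 were below -0.5 under all 6, which argues against the choice among these scalings as the whole cause. Among the 13, Adrb3 (-0.59 with quantile scaling) rests on day 8 alone, with both media at the floor on days 2, 4 and 6. The chickpea arrays were dimmer from day 4 on. The 57 genes outside the list with like control levels had a median difference of 0.144 (quartiles -0.53 and 0.76, against -2.03 for the markers). Quantile scaling had already given all arrays the same distribution of values. That test could therefore hardly come out otherwise and does not decide on dimmer signal. Without scaling, the median of all tested genes was -0.32, against -2.79 for the markers. Of the 8 splits, 1 (the real one) called 36 genes and the highest other 0, too few splits for a share under 0.05. The other splits swap the media on some days, which turns a difference shared by the days into spread. Few calls would follow there whatever the cause of the difference. An effect of the chickpea medium stays open as a hypothesis: 6 markers passed the limma test over the 4 day pairs, with 1 culture per medium and day.

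The number of genes called higher may come from the scaling: all 5 other scalings changed it from 21 by over 1.5 times, to between 0 and 13. Which scaling is right is not known, so the size of these increases stays open.

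On day 2, Trib3, Pck2 and Eif4ebp1, chosen after their values were seen, were 4.64, 2.84 and 2.38 higher with chickpea. These genes may respond to amino acid or stress sensing, but 4 other measured genes of that response had a median of 0.202, with Vegfa at 2.00 and Vldlr at -0.34, so the test did not decide.

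Of 3 scanner wells without a sample name, used in no comparison, 1 had 69.16% and another 71.03% of gene spots above the limit, against 0.813% of empty and negative control spots.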

How the results depend on the processing

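The settings with no floor and with a filter limit of 20 units were chosen after seeing the data, and the other settings before the data were examined. The chickpea count of 36 was 7 on the deposited values, 15 unscaled, 114 with array weights, 73 without the day block and from 0 to 71 when 1 day was left out. The differentiation count of 5 was 3 with median scaling, 0 with control gene scaling, 0 deposited, 0 unscaled, 2 above the limit on every array, 10 with trend and robust eBayes, 32 with array weights, 0 on the control arrays alone (77 at an unadjusted p under 0.05, limma), from 0 to 28 leaving out 1 array, 9 with no floor and 8 with the limit of 20. The count changing with day was 3 with median scaling and 0 deposited (54 at an unadjusted p under 0.05, limma). With a 1.5-fold threshold the genes differing were 144 on day 4, 123 on day 6 and 108 on day 8. On the deposited values, the genes at least 2-fold from day 0 in control medium were 137 on day 2 and 105 on day 4. These values are scaled to Gapdh, and their median was 63.3 on control day 0, 31.5 on day 2 and 52.4 on day 4. On day 8 against day 0 the median of all tested genes was -1.08 on the deposited values, with Gapdh at 0.07. Unscaled, these were 0.48 and 1.70. Lists past camera were 1 (chickpea) and 3 (differentiation) with median and with control gene scaling. With an estimated correlation none held (adjusted p = 0.544 and 0.995 for chickpea, 0.356 and 0.529 for differentiation). Fewer arrays or genes enter some of these; otherwise the cause was not tested. The slopes on the differentiation axis kept direction with median scaling. Removing the filter added 0 tested genes to the chickpea fit, so it tests nothing. No background correction and slide as a block were not run, since values were already background-subtracted and 1 slide was scanned.

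Of the 21 genes called higher with chickpea, 20 were above 0 under all 6 scalings. The genes below did not pass the comparison in which they reversed. Chickpea, median scaling: Acaca -0.028, Irs1 -0.083, Ucp2 -0.14. Control genes: Cebpb -0.19, Cd36 -0.087, Acaca -0.44, Ccl2 -0.17, Il6 -0.076, Irs1 -0.49, Ucp2 -0.55. Deposited: Acaca -0.094, Irs1 -0.19, Ucp2 -0.21. Unscaled: Cebpb -0.045, Acaca -0.29, Ccl2 -0.022, Il6 -0.26, Irs1 -0.36, Ucp2 -0.46. Leaving out 1 day: Cd36 from -0.20 (without day 2) to 1.36 and Ucp2 from -0.34 (without day 8; -0.042 without day 4, -0.093 without day 6) to 0.72. Differentiation, median scaling: Cebpb 0.043. 75th percentile: Cebpb 0.072, Ucp2 0.0035. Control genes: Cebpb 0.042, Il6 0.19. Deposited: Srebf1 -0.025, Acaca -0.33. Unscaled: Cebpb 0.86, Cebpd 0.45, Il6 0.79, Insr 0.63, Irs1 0.16, Ppargc1a 0.036, Ucp2 0.41. Leaving out 1 array: Cebpd from -0.77 to 0.17 and Ucp2 from -0.85 to 0.74, each reversed without control day 8. The cause was not tested. Signal over background limits Cfd, Adipoq, Retn and Hp, above the limit on 1, 2, 0 and 0 of 4 chickpea arrays.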

Other observations

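Other genes higher with chickpea under quantile scaling were Gsk3b by 0.96 ± 0.20 (SE), Rhoq by 1.15 ± 0.21, Jak2 by 0.91 ± 0.20 and the adiponectin receptor Adipor1 by 0.95 ± 0.16, each on 4 of 4 days and chosen after their values were seen. Of the 21 genes called higher, 20 were above 0 under all 6 scalings, and 15 of the 15 called lower were below 0.

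The Gapdh probes at the 5' and 3' end, on the deposited scale, differed by between -0.06 and 0.09 (log2) on the 9 arrays.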
